A study of Arabidopsis thaliana with 2 samples.

How the data were processed

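RNA was measured in 2 libraries of Arabidopsis thaliana semi-in-vivo pollen tubes, 1 of wild type (WT) and 1 labelled drop1- drop2- (drop), each from tubes of 2 stigmas pooled in lysis buffer and carried through Smart-seq2, per the labels' protocols. The treatment text speaks of double mutant grains for both samples, so the genotype of each library was taken from its genotype label. Expression was deposited by the authors as FPKM, fragments per kilobase of transcript scaled to mapped fragments, with 1 column per library, per the file headers. TopHat2 2.0.14, Cufflinks 2.2.1 and the genome build TAIR10 are listed in the submitters' processing notes. Their parameters, the annotation release and any further scaling are not given in the sources used here.

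The deposited drop column does not behave as FPKM scaled to mapped fragments alone. Whether the WT column does was not settled, because the sums given next leave out part of the genes. Over 17910 genes with a single annotated transcript of at least 600 bases, FPKM times length in kb summed to 0.815 times the largest sum that scale allows in WT and to 1.94 times that sum in drop. The median of log2(drop/WT) over the 11359 genes above 0 in both libraries was 0.06, while it was 1.11 over the 1935 genes with at least 10 FPKM in both. For this reason each result was also computed with the libraries rescaled. Among 2790 genes between 0 and 1 FPKM in both libraries, the most frequent ratio of drop to WT was 1.80, with 292 genes in its bin of 0.1 log2 units against a median of 45 genes per bin around it. That ratio is close to the 1.79 between the values of 1 fragment, estimated from the lowest peak of FPKM times length in transcripts of at least 3 kb (44 genes in WT, 84 in drop). Fragment numbers given in the text are deposited FPKM times annotated length divided by the value of 1 fragment, and are approximate because Cufflinks can correct lengths and divide fragments between genes. PCR copies were not marked by molecular identifiers, so fragments are not independent molecules.

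Genes were compared as log2((drop FPKM + 1)/(WT FPKM + 1)), a scale that understates the ratio of genes with low values. With 1 library per genotype no test across samples and no p-value was computed. A gene counted as higher or lower in drop when it passed 2-fold on this scale and had FPKM of at least 10 in at least 1 library. No fold is given against a value of 0, which can be a failed estimate, and such a gene is described as listed at 0. Fold values in the text are ratios of deposited FPKM unless a log2 ratio is named.

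The 15 gene lists (234 genes) and 19 families defined by words in gene descriptions were written before the data were examined, as were the groups, the size rule, most alternative settings and the rule for naming genes. All 234 list genes were found in the table. For 10 of them the names table gave another name, and these were left out of list medians. List members with FPKM of at least 1 in at least 1 library were measured. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size (seed 1), with each member replaced by a gene from the 200 nearest in mean log2(FPKM + 1). The percentile describes these libraries and is not a p-value. Intervals of a median are 95% order-statistic intervals over genes. Of the families, 18 had at least 10 measured members and were used, and the transposable element family, with 4, was not. Family words can also catch genes with other roles, such as mitochondrial and plastid ribosomal proteins.

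The naming rule took the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a name and at least 10 FPKM in at least 1 library. From each list it took the 2 members with the highest mean FPKM and the 2 with the largest absolute log2 ratio among members with at least 10 FPKM in at least 1 library, and it allowed any member of the sperm list. Other genes are named only where the text says so, apart from RALFL15 and AGP23, which were chosen after their values were seen to show the range of the table.

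Gene symbols and descriptions were taken from the RefSeq annotation of TAIR10.1, which differs from the authors' TAIR10, so no coordinates are given. Of the 33557 gene identifiers, 32810 matched that annotation, and of the 747 others 279 were organelle genes. Genes with close paralogs, such as the RALF-like, sucrose transporter, Rubisco small subunit, actin and lipid transfer genes, and genes that overlap others, are uncertain because fragments can be shared between them.

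The alternatives were pseudocounts of 0.1 and 10, other filters, a 4-fold rule, leaving out genes at 0, and 4 other scalings: equal sums, a median ratio of 1 over genes with at least 10 FPKM in both libraries, quantile normalization, and equal sums without the 50 genes of highest mean and the organelle genes. In the scalings the filter stayed on deposited values, except that percentiles under another scaling took the members with FPKM of at least 1 after it. Transcripts of at least 500 bases and lists with all members were added after seeing the data. On simulated libraries with noise of SD 0.3 on the log2 scale, the 2-fold rule recovered 100% of 50 genes at each log2 change of -3, -2, 2 and 3 and passed 0.072% of 2788 unchanged genes. A list of 20 genes changed by -3 lay at percentile 0 and 5% of 100 unchanged lists lay in the outer 5% of random lists, each over 8877 genes. The simulated libraries had no difference in scale, no shift with level and no lost transcripts. Their rates follow from the chosen noise and are not error rates for the real libraries. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.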

Results

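Arabidopsis thaliana pollen tubes were profiled by RNA sequencing after semi-in-vivo growth, in which pollen germinates on a cut pistil and the tubes then grow out of the style onto solid medium. The series compares wild-type tubes (WT) with tubes labelled drop1- drop2- (drop), a double mutant, and its title concerns sperm cells as cargo carried by the tube. Each genotype has 1 library, so no value has a replicate error, no test across samples was run, and "higher" or "lower" below describes these 2 libraries. Although the labels speak of single cells, their protocol describes tubes from 2 stigmas pooled in lysis buffer for 1 Smart-seq2 library of polyadenylated RNA. Tubes were cut when they had grown 300 to 400 µm out of the style, from stigmas pollinated with 500 to 600 hand-picked grains 36 h after emasculation. The names DROP1 and DROP2 were found for 0 genes in the names table used, so the level of the mutated genes was not checked and the genotype rests on the labels.

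The table lists 33557 genes in FPKM. FPKM reached at least 1 for 8633 genes in WT and 7331 in drop. The deposited FPKM summed to 1299600 in WT and 3668030 in drop, a ratio of 2.82. Depth is not given with FPKM, but the smallest steps of the values give an estimate: in transcripts of at least 3 kb, 1 fragment was worth about 0.136 FPKM kb in WT and 0.244 in drop. At that step, the genes with a single annotated transcript held about 7060000 fragments in WT and 10130000 in drop. Across all genes, log2(FPKM + 1) of the libraries had a Pearson r of 0.87 and a Spearman rho of 0.78. Genes are not independent replicates, and r was 0.65 over the 3633 genes with FPKM of at least 10 in at least 1 library. The RALF-like peptide gene RALFL15 (AT2G22055) stood at 74880 FPKM in WT and 265788 in drop, and the arabinogalactan protein gene AGP23 (AT3G57690) at 40162 and 108086.

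Among those 3633 genes, 1650 were at least 2-fold higher and 1015 at least 2-fold lower in drop as deposited, so 61.9% of the genes past 2-fold were higher. This split depends on the scale. With both libraries set to the same sum, 314 were higher and 1564 lower, or 16.7% higher, and with a median ratio of 1 over genes of at least 10 FPKM in both, 579 were higher and 1392 lower, or 29.4% higher. Equal sums without the 50 highest genes and the organelle genes gave 571 higher and 1393 lower, or 29.1% higher. The factors behind these scalings are -1.497 at equal sums and -1.11 for each of the others on the log2 scale, and with 1 added to each FPKM they move genes of low level by less. The median log2 ratio over the 3633 genes was 0.81 as deposited, -0.58 at equal sums, -0.24 under the median-ratio scaling and 0.40 after quantile normalization. Under all 5 scalings, the deposited values included, 312 genes were at least 2-fold higher and 992 at least 2-fold lower in drop. The log2 ratio also went with the level of a gene. For this, log2(drop/WT) was taken without a pseudocount over genes above 0 in both libraries. Its median was -0.15 over the 3731 genes with a mean log2(FPKM + 1) below 1. It was -0.37 over the 2707 genes with a mean from 1 to 2, and 1.85 over the 170 genes with a mean of at least 10. Each list below is therefore set against random lists of the same size and expression, which were not matched on transcript length.

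Transcripts of the sperm cells were far lower in drop. Of 22 genes in the sperm list, 17 were measured, and 16 of these were at least 2-fold lower and 0 at least 2-fold higher in drop. The median log2 ratio was -3.51, against 0.50 for matched random lists, and 0 of 10000 random lists lay as low. That is 11.4-fold lower in FPKM + 1, which understates the fold in FPKM of members with low values. The median was -3.83 at equal sums and between -3.42 and -3.88 under the other scalings. Together the measured members held 3.95% of the summed FPKM in WT and 0.0939% in drop.

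The most abundant sperm transcript was that of the F-box gene DAF1 (AT3G62230), a target of the germline regulator DUO1, with 32693 FPKM in WT and 2748 in drop, an 11.9-fold difference. PCR11 (AT1G68610) was at 8504 FPKM in WT and 220.2 in drop, or 38.6-fold lower, the zinc finger gene DAZ3 at 6897 and 290.3, and DAN1 (AT3G04620) at 2453 and 84.8. GEX1, which acts in gamete nuclear fusion, was at 602 FPKM in WT and 88.7 in drop. The gamete fusion gene HAP2 was at 11.5 and 0.570, GEX3 at 34.6 and 1.62, the tetraspanin genes TET11 at 25.3 and 1.17 and TET12 at 44.2 and 1.96, and KPL at 19.6 and 0.771. SSP, DAA1 and OPT8 were lower in the same way, and DUO1 itself was at 8.34 FPKM in WT and 0.760 in drop. DAU2 and MGH3, the male-gamete histone H3, were listed under other names and left out of the median, and stood at 111 and 2.59 FPKM and at 283 and 12.8. Over the 13 list members with at least 10 FPKM, drop held a median of 4.64% of the WT value as deposited, from 2.59% for PCR11 to 14.7% for GEX1. At equal sums that median was 1.65%. For 8 of these 13 the drop value rests on fewer than 20 estimated fragments.

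**Figure D1:**
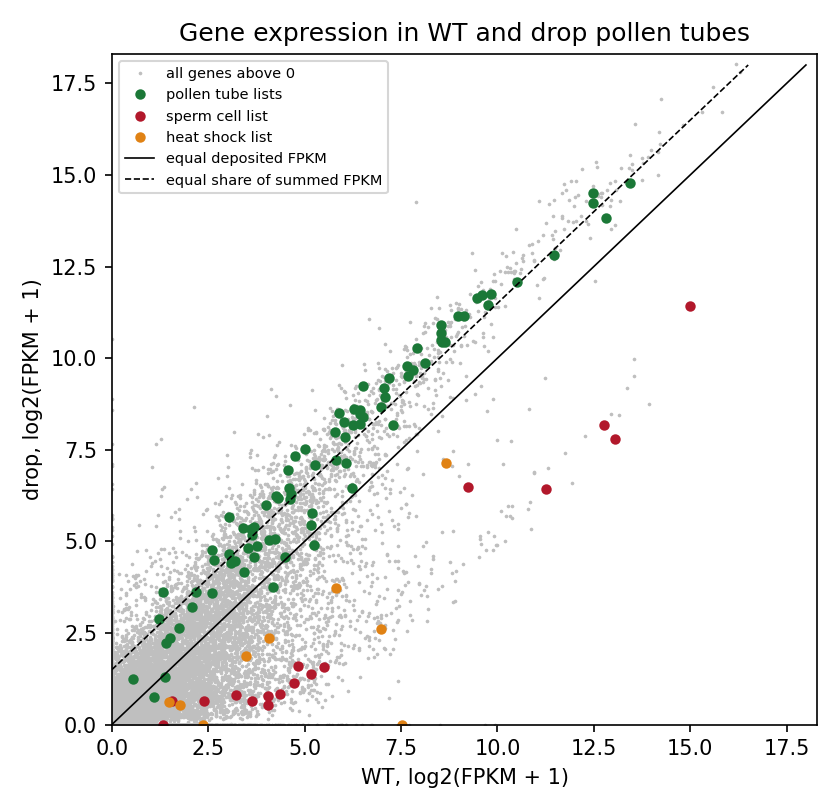
Deposited expression of each gene above 0 in at least 1 library, as log2(FPKM + 1) in WT on the x axis and drop on the y axis, with 1 library per genotype and list members with FPKM of at least 1 coloured. The solid line marks equal FPKM and the dashed line equal shares of the summed FPKM. Pollen tube genes lie along the dashed line, and sperm genes such as DAF1 (32693 FPKM in WT, 2748 in drop) lie below both lines.

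Genes of the cell cycle and of chromatin in the germline were lower as a list, with exceptions. Of 7 measured members, 5 were at least 2-fold lower in drop, with a median log2 ratio of -1.66 that lay at percentile 0.40 of matched random lists and an interval over genes of -3.34 to 0.01. At equal sums the list lay at percentile 2.58, and with no filter its median was -0.77. The chromatin remodeller DDM1, listed as CHR1 (AT5G66750), was at 43.7 FPKM in WT and 3.42 in drop. The other members at least 2-fold lower were below 10 FPKM in both libraries. Their drop values rest on fewer than 20 estimated fragments. The cyclin CYCB1;2 (AT5G06150) was at 239 and 241, a log2 ratio of 0.01 as deposited that was -1.47 at equal sums.

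Genes of the vegetative pollen tube were higher in drop as deposited, and by much less at equal sums. Over the 5 pollen tube lists combined, 65 of 83 measured members were at least 2-fold higher and 0 at least 2-fold lower in drop, with a median log2 ratio of 1.79 (95% order-statistic interval over genes 1.62 to 1.88). Matched random lists had a median of 1.16, and 0 of 10000 lay as high. At equal sums the median was 0.30 (0.16 to 0.41), 5 members were at least 2-fold higher and 5 at least 2-fold lower.

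Receptors of pollen tube guidance and their partners had a median of 1.90, at percentile 99.4 of matched random lists, and 10 of 14 were at least 2-fold higher. The cation/proton exchanger CHX23 (AT1G05580) was at 558 FPKM in WT and 2252 in drop, CHX21 at 22.9 and 122, the receptor kinase MDIS1 (AT5G45840) at 76.1 and 393, and PRK3 at 7.19 and 49.4. At equal sums the list's median was 0.47. Genes of tube integrity and bursting had a median of 2.12, at percentile 98.5, with 16 of 17 at least 2-fold higher, and a median of 0.62 at equal sums. Within that list, the receptor kinase ANX1 (AT3G04690) was at 26.0 FPKM in WT and 160.3 in drop, the transcription factor MYB120 (AT5G55020) at 90.2 and 604, and LLG2 at 904 and 3421. The peptide gene RALFL4 was at 2835 and 7233, a log2 ratio of 1.35 that turned to -0.15 at equal sums and -0.05 after quantile normalization.

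Tip growth signalling genes had a median of 1.66, at percentile 99.4, with 17 of 24 at least 2-fold higher, and 0.19 at equal sums. The small GTPase ROP1 (AT3G51300) was at 200.6 FPKM in WT and 889 in drop, the calcium-dependent kinases CPK17 at 222 and 818 and CPK34 at 58.6 and 363, and the syntaxin SYP124 at 31.2 and 182. Cytoskeleton genes had a median of 1.69, at percentile 94.1, with 13 of 19 at least 2-fold higher, and 0.20 at equal sums. They included the tubulin TUB9 at 709 and 3211, the actin ACT11 at 144 and 707, the actin depolymerizing factor ADF7 at 857 and 2772 and the villin VLN5 at 1.497 and 11.2. Cell wall genes did not stand apart from genes of like level: their median of 1.53 lay at percentile 44.6 and was 0.06 at equal sums, although 9 of 9 were at least 2-fold higher as deposited. The pectin methylesterase VGD1 was at 5688 FPKM in WT and 19160 in drop and the inhibitor PMEI1 at 5724 and 23096. AGP11 was at 11006 and 28010, a log2 ratio of 1.35 that turned to -0.15 at equal sums and -0.12 after quantile normalization.

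**Figure D2:**
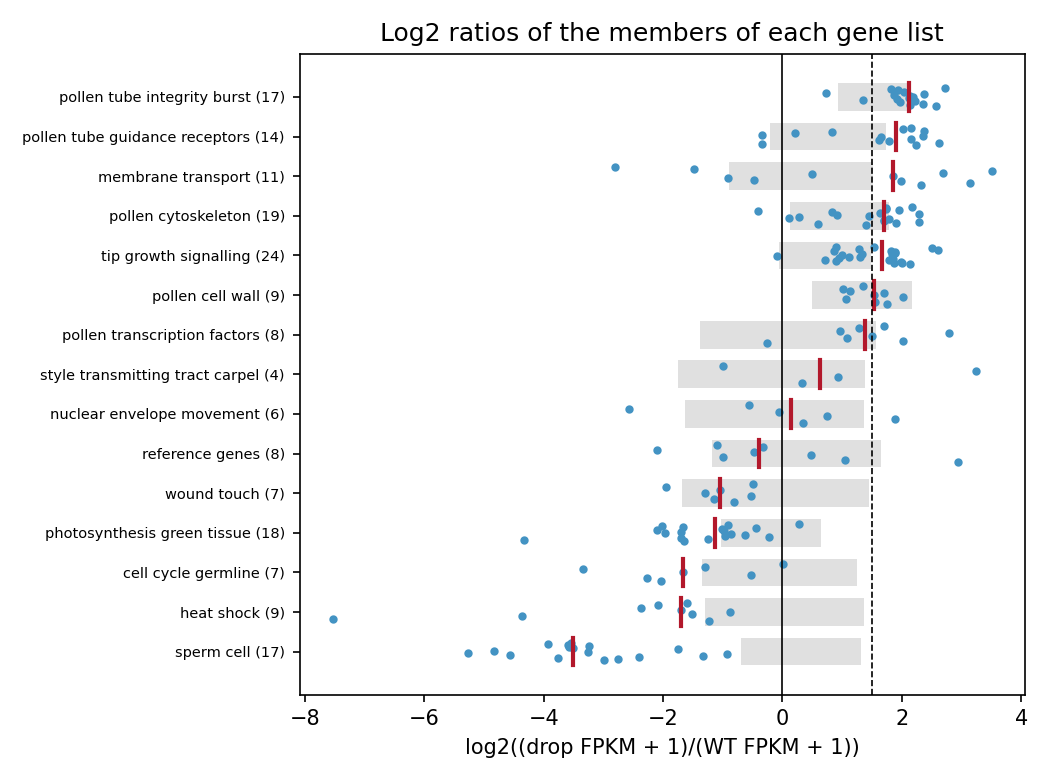
Log2((drop FPKM + 1)/(WT FPKM + 1)) of each measured member of the 15 gene lists as points, with the number of members in brackets and the list median as a red bar. Grey bars span the central 95% of medians of 10000 random lists of matched expression, the solid line is equal FPKM and the dashed line equal shares of the summed FPKM. The sperm list has the lowest median, -3.51, and the integrity list the highest, 2.12.

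Membrane transport genes went both ways, with 6 of 11 at least 2-fold higher and 2 at least 2-fold lower in drop, and a median of 1.85 (interval over genes -1.48 to 3.14) that was 0.36 at equal sums and 0 with no filter. It lay at percentile 99.8 of matched random lists as deposited, but at 82.2 after quantile normalization. The hexose transporters STP10 (AT3G19940) and STP11 (AT5G23270) were at 434 and 2.41 FPKM in WT and at 2807 and 37.8 in drop. The proton pumps HA8 and HA6 were at 1317 and 3.45 in WT and at 5196 and 38.1 in drop. Pollen transcription factors had a median of 1.39 at percentile 94.5 as deposited and 98.2 after quantile normalization, with 6 of 8 at least 2-fold higher, and 0.10 at equal sums. The MADS-box genes AGL94 and AGL30 stood at 26.2 and 29.0 FPKM in WT and at 186 and 119.9 in drop. Genes of nuclear envelope movement had a median of 0.14, at percentile 53.5, which was below 0 under each other scaling. The outer nuclear membrane gene WIT1 was at 30.0 and 38.2 FPKM, while the inner nuclear envelope gene SUN1 (AT5G04990) was at 66.1 in WT and 10.3 in drop, lower under each scaling.

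Among the 12 named genes with the highest log2 ratios, the cysteine-rich peptide gene LCR83 (AT5G54225) was at 1464 FPKM in drop and listed at 0 in WT, as were SAUR28 at 51.9, PDF1.5 at 47.9 and RALFL10 at 34.7. RALFL16 (AT2G32835) was at 237 FPKM in WT and 19784 in drop, or 83.5-fold higher. The methyltransferase XPL1 (AT3G18000) was at 1.43 and 220.0, GASA1 at 1.06 and 131, PRP4 at 1.46 and 84.7, the copper transporter COPT2 at 7.94 and 254, and CYS2 at 0.638 and 43.0. The sucrose transporters SUC7 and SUC8 were at 16.6 and 18.1 FPKM in WT and at 570 and 497 in drop, and as close paralogs they may share reads. All 12 were at least 2-fold higher under each scaling.

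Among the 12 named genes with the lowest ratios, the small heat shock gene HSP17.6II (AT5G12020) was at 185 FPKM in WT and listed at 0 in drop, as were PSK6 at 169, CLE14 at 79.0, LTPG1 at 59.0, GSTF2 at 46.5 and Hsp70b at 38.7. The lipid transfer genes LTP3 and LTP4, which are close paralogs, were at 144 and 85.3 FPKM in WT and at 0.650 and 1.45 in drop, and SMAP2 was at 169 and 1.29. PCR11 of the sperm list completes the group with MIR780 and U12, at 174 and 171 FPKM in WT and listed at 0 in drop, which are short non-coding genes in a library made from polyadenylated RNA. Across all genes, 10 with at least 100 FPKM in WT were listed at 0 in drop and 6 the other way.

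Heat shock genes were lower in drop, with 8 of 9 measured members at least 2-fold lower and a median log2 ratio of -1.70 at percentile 0.95 of matched random lists. At equal sums 9 of 9 were lower, with a median of -2.63. HSP17.4 was at 407 FPKM in WT and 141 in drop and HSP17.6A at 125 and 5.14. Wound and touch genes had a median of -1.05 at percentile 7.74, with 4 of 7 at least 2-fold lower. At equal sums 7 of 7 were at least 2-fold lower with a median of -1.80, and under the median-ratio scaling 7 of 7 with a median of -1.79. Their zinc finger gene RHL41 was at 87.8 and 42.0, JAZ1 at 31.2 and 21.8 and TCH2 at 16.8 and 9.12.

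Photosynthesis genes of green tissue had a median of -1.13 at percentile 1.46, with 10 of 18 at least 2-fold lower in drop and 0 at least 2-fold higher, and at equal sums a median of -1.82 with 16 of 18 lower. The Rubisco small subunit genes RBCS3B and RBCS1A were at 83.7 and 18.9 FPKM in WT and at 3.22 and 5.34 in drop, and PSBO1 at 12.5 and 3.23. Organelle genes held 0.0489% of the summed FPKM in WT and 0.00739% in drop. Of 14 style and carpel genes only 4 were measured, with a median of 0.63 at percentile 82.1 that was -0.61 at equal sums; HAF, listed as CES, was at 43.8 and 55.1 FPKM. Reference genes did not share a direction, with 2 of 8 at least 2-fold higher and 3 at least 2-fold lower and a median of -0.40 at percentile 13.0. At equal sums 1 was at least 2-fold higher and 5 lower, with a median of -1.24, and under the median-ratio scaling the counts were the same and the median -1.13. The actin ACT2 was at 119 FPKM in WT and 926 in drop, higher under each scaling, and GAPC1 at 74.2 and 16.5, lower under each scaling. The polyubiquitin gene UBQ10 was at 331 and 682, a log2 ratio of 1.04 as deposited that was below 0 under each other scaling.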

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

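The transcript length and full-list alternatives were chosen after seeing the data, and neither changed a direction. No paired analysis was possible because each genotype has 1 library. The number of genes at least 2-fold higher in drop was 1650 as deposited, 314 at equal sums, 579 under the median-ratio scaling and 571 at equal sums without the 50 highest and organelle genes, where the scaling itself sets the difference. With FPKM of at least 1 or no filter it was 2605, with FPKM of at least 50 it was 937, and at 4-fold it was 638. With 1 added to each FPKM, a gene below 1 FPKM in both libraries cannot pass 2-fold, so those 2 settings count the same genes. The number lower was 1015 as deposited, 1564 at equal sums, 3001 with FPKM of at least 1 or no filter and 299 with FPKM of at least 50. Fewer or more genes enter under another filter.

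The sperm list's median of -3.51 was -4.25 with a pseudocount of 0.1, -1.64 with 10, -3.83 at equal sums, -3.88 under the median-ratio scaling and -3.88 at equal sums without the 50 highest genes; a larger pseudocount shrinks low values by construction. The pollen tube lists' median of 1.79 was 1.53 with a pseudocount of 10, 0.30 at equal sums, 0.69 under the median-ratio scaling, 1.08 after quantile normalization and 0.68 at equal sums without the 50 highest genes. The correlation of the libraries was 0.87 over all genes, 0.78 over genes with FPKM of at least 1 and 0.65 with at least 10. Genes detected numbered 15150 in WT and 12942 in drop with FPKM above 0, and 2834 and 2734 with at least 10.

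Of 62 named genes at least 2-fold apart as deposited, log2 ratios turned sign for RALFL4 (-0.15 at equal sums, -0.054 after quantile normalization), AGP11 (-0.15 and -0.12 under the same scalings) and UBQ10 (-0.45 at equal sums, -0.061 under the median-ratio scaling, -0.057 after quantile normalization and -0.069 at equal sums without the 50 highest genes). WIT1, HAF and CYCB1;2, less than 2-fold apart as deposited, also turned, to -1.08, -1.11 and -1.47 at equal sums. These turns are set by the scaling. Of all 67 named genes, 11 moved by less than 1.5-fold at equal sums. Of the 15 lists and the combined pollen tube list, none whose median lay in the outer 5% of random lists changed sign under any scaling, pseudocount or filter tried, but the membrane transport list's median was 0 with no filter. Depth limits the low sperm values in drop, most of which rest on few estimated fragments.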

Other observations

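All tests in this part were chosen after the results were seen, apart from the family medians. Several families defined by gene descriptions lay in the outer part of matched random lists as deposited. Core histone genes were lower in drop, with 23 of 42 measured members at least 2-fold lower. Their median log2 ratio was -1.14, at percentile 0.01 of matched random lists. MGH3, also a gene of the sperm list, had the largest change as deposited (283 FPKM in WT, 12.8 in drop). At equal sums AT2G37470 was lower than MGH3, with log2 ratios of -5.78 and -5.61. Ribosomal protein genes had a median of -0.93 at percentile 0, with 107 of 235 at least 2-fold lower as deposited and 183 of 235, with a median of -1.59, at equal sums. Photosystem and light-harvesting genes had a median of -1.37 at percentile 0.01, and heat shock proteins one of -0.81 at percentile 0.34. At equal sums the medians of the histone, photosystem and heat shock families were -1.55, -1.68 and -1.32. These 4 medians were below 0 under each scaling, with percentiles of at most 0.18 at equal sums, under the median-ratio scaling and after quantile normalization. Defensin-like and other cysteine-rich peptide genes had a median of 1.59 at percentile 99.97, above 0 under each scaling but at percentile 28.9 after quantile normalization, and took 23.1% of the summed FPKM in WT and 29.7% in drop. The random lists were not matched on transcript length. Among single-transcript genes with at least 10 FPKM in both libraries, the deposited median was 2.80 over 24 genes below 300 bases. It was 1.13 over 107 genes from 300 to 600 bases and lowest, at 0.72, over 305 genes from 600 to 1000 bases. From there it rose with each class to 1.76 over 19 genes of at least 3000 bases. At equal sums these last 2 medians were -0.72 and 0.29. Sugar transporters had a median of 0.86 at percentile 99.96 and pectin lyases and polygalacturonases one of 1.38 at percentile 99.8, and at equal sums these were -0.29 and -0.02. After quantile normalization they lay at percentiles 99.2 and 61.3. Cytochrome P450 genes had a median of 0.47 at percentile 99.3 that was -0.64 at equal sums over the same 31 members. Over the 18 members with FPKM of at least 1 after that scaling it was -1.16, at percentile 51.0. The other families lay between percentiles 3.67 and 97.45 as deposited, but not all did under other scalings: RING ubiquitin ligases lay at 99.92 under the median-ratio scaling, and pectin methylesterases at 0.85 after quantile normalization. Their medians were 0.35 for pectin methylesterases, -0.35 for leucine-rich repeat receptor kinases, -0.66 for F-box proteins, 0.79 for arabinogalactan proteins, 0.14 for peroxidases, 0.29 for EF-hand and calmodulin genes, 0.19 for actin-binding proteins, 0.19 for RING ubiquitin ligases, 0.52 for lipid transfer proteins and 0.23 for aquaporins, and at equal sums each of these was below 0 over the same members. For leucine-rich repeat receptor kinases this depends on the filter: over the 18 members with FPKM of at least 1 after that scaling the median was 0.08, at percentile 99.84.

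Abundant WT transcripts were spread unevenly over the ratio. Of 635 genes outside the sperm list with at least 100 FPKM in WT, 10 were listed at 0 in drop. In bins of 1 log2 unit of drop/WT without a pseudocount, 2 lay below -6, and the bins from there to 4 held 22, 64, 27, 19, 23, 29, 80, 206, 142 and 9 genes, with 2 above. Between 2.59% and 14.7% of their WT level, the range of the 13 sperm list members with at least 10 FPKM, stood 105 genes. GEX1 alone sets the upper edge of that range. With the next member, DAF1 at 8.41%, as the edge, 85 genes lay within it, and DAU2, left out of the list median for its name, stood below it at 2.33%. The 105 genes held 9.17% of the summed FPKM in WT and 0.165% in drop. The genes named next were picked after their values were seen, without a rule, and do not stand for the 105. AT4G14315, described as an uncharacterized protein, was at 15734 FPKM in WT and 427 in drop. The cyclin CYCD7;1 was at 7867 and 358, the F-box gene AT1G80470 at 4974 and 234.4, and the aquaporin TIP5;1 at 3462 and 171. The histone gene AT2G37470 was at 2536 and 126 and the replication origin gene ORC6 at 1322 and 60.9. The cyclin-dependent kinase subunit CKS2 was at 826 and 26.4, and the ribonucleotide reductase gene TSO2 at 735 and 22.9. The range also held AT1G34095 and AT1G75870, described as uncharacterized proteins, at 11931 and 1004 and at 11886 and 726. Others with different descriptions were EIN3 at 864 and 37.4 and HSP17.6A at 125 and 5.14. They are listed here as values, and where in the tube they are expressed was not tested.

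Pollen tube genes were higher in drop as deposited, and higher than genes of like level. For their place above genes of like level, a scaling that goes with level alone is argued against as the whole cause. The combined lists lay at percentile 100 of matched random lists as deposited and after quantile normalization, which moved other sets such as membrane transport from 99.8 to 82.2. Scalings by 1 factor per library move a list together with its matched lists and do not bear on this. The point covers the combined lists and not each of them. After quantile normalization the guidance, integrity and tip growth lists lay at 99.7, 99.2 and 99.1, but the cytoskeleton and cell wall lists at 83.9 and 36.05. Transcript length was not matched, and a scaling that goes with length was not tested. In the length classes given above, from 600 bases up, the deposited median rose from 0.72 at 600 to 1000 bases to 1.76 at 3000 bases or more. Genes of like level also include transcripts far lower in drop, so the percentile does not tell a higher list from a lower pool. For the rise itself, a change in the tubes as the whole cause is argued against. FPKM times length summed to 1.94 times the largest sum that scaling to mapped fragments allows in drop, and to 0.815 times in WT. A change in the tubes does not lift a sum above that limit. The size of the part due to scaling was not settled, because the amount of RNA per library was not measured. The median log2 ratio of 1.79 was 0.30 (0.16 to 0.41) at equal sums. A share left free by transcripts that were lower in drop cannot be weighed against the deposited rise. That rise includes the 2.82-fold difference between the column sums, which a shift of shares within a fixed sum does not produce. The loss of every gene with a lower share in drop, 43.5% of the WT sum, raises all others by 0.82. That this lies below the interval of 1.62 to 1.88 restates the difference in sums. The scaling and a freed share acting together were not tested. For the 0.30 at equal sums the freed share stays open. The loss of the 1085 genes at least 4-fold lower there raises all others by 0.28, but they were chosen on the scale that gives the 0.30, so this does not decide. An effect of the genotype on the vegetative cell stays open and untested.

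Heat shock genes were lower in drop, and lower than genes of like level. For their place below genes of like level, a scaling that goes with level alone is argued against as the whole cause. The percentile was 0.95 as deposited and 0.19 after quantile normalization, and the median was below 0 under each scaling. Transcript length was not matched here either, and a scaling that goes with length was not tested. Counting error at the depth of the drop library was weighed next. All 9 measured members lay below the 95% Poisson range of the fragments due in drop at their WT share. The median was 376 due and 14.9 estimated. The numbers due are set at equal sums, where 9 of 9 members were at least 2-fold lower. A member that much lower with at least 20 fragments due falls below the range in any case. The result thus shows only that enough fragments were due for counting error alone not to give such values. Members listed at 0 in drop, such as HSP17.6II, can be failed estimates. That range covers counting error only and takes fragments as independent, which PCR copies are not. A loss of molecules before or during amplification was not tested. RNA of pistil cells in the WT library may contribute and cannot be told apart from a change in the tubes, because the lists of other tissues did not move together and few style genes were measured. The green tissue list was lower in drop too, at percentile 1.46, but the style and carpel list was not, with a median of 0.63 at percentile 82.1 over 4 members (interval over genes -0.99 to 3.25) that was -0.61 at equal sums. The green tissue list's most abundant gene, RBCS3B, was at 83.7 FPKM in WT, 18 of its 24 genes were measured in these tubes and no pistil library was used here. Genotype and the handling of each library coincide with 1 library per genotype, so neither was tested.

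Sperm transcripts remained at a low level in drop, a median of 4.64% of WT as deposited and 1.65% at equal sums. Fragments of the finished WT library read into the drop library as the whole cause would keep 1 ratio, with a quotient of at most 1.5 taken as counting error. Among 5 members with at least 100 estimated fragments in drop the highest ratio was 5.69 times the lowest, and without GEX1, the highest, 3.25 times. Transfer before amplification was not tested. The SD of log2(drop/WT) was 0.67 over 13 sperm members and 0.68 over 75 pollen tube members. Draws of 13 of the latter ranged from 0.35 to 0.97 (central 95%). These values do not decide on a common small share of sperm RNA. The spread of pollen tube members is not the spread that such a share allows. In addition, 8 of the 13 sperm values in drop rest on fewer than 20 estimated fragments. Such a share could come from a few tubes that carry sperm cells or from low expression in the vegetative cell, and bulk tubes do not separate these.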
